A study of Rattus norvegicus with 30 samples.

How the data were processed

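Gene expression was measured in 30 culture wells of primary rat hepatocytes, 1 array per well, on the GeneChip Rat Genome 230 2.0 array, which reads transcripts as probe sets of short oligonucleotides. The cells were bought frozen, came from male Sprague Dawley rats, were plated on collagen under a Matrigel overlay, and were dosed on day 3 of culture. The labels give vehicle, 300 µM or 3000 µM phenobarbital and harvest after 24 h or 48 h, which makes 6 groups of 5 wells. The vehicle is called water in the sample titles and culture medium in the field that names the agent. The labels number no animals or donors, so wells are the replicates throughout, and spread between wells says nothing about spread between animals. A running number in the titles falls into sets of 6 with 1 well of each group, but the labels do not say what it counts, so these sets served as a block in an alternative only.

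The deposited values are probe set intensities on a linear scale, which the labels tie to the MAS5 software without a version or a target value. The mean signal of each array, after leaving out 2% of values at each end, was 1500.6 to 1500.7 on all 30 arrays, so the authors scaled each array by a single factor. No detection calls and no genome positions came with the values. The table held 31099 probe sets, of which 57 were controls, 20826 had 1 gene symbol, 436 had several and 9780 had none in the annotation available. The lowest signal was 0.251, the highest 197200, and no value was at or below 0. Array medians lay between 349 and 424.9.

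Signals were put on the log2 scale without an added constant. A probe set was tested if the highest of its 6 group means reached the median of all values, a log2 signal of 8.58 or a signal of 384, and changes from or to a group below this level are imprecise. This left 16596 probe sets, 12971 with 1 symbol, 331 with several and 3294 unnamed, for 9831 genes. limma 3.58.1 in R 4.3.3 fitted the 6 group means over all 30 arrays (lmFit, contrasts.fit, and eBayes with trend and robust estimation), with Benjamini-Hochberg adjustment within a comparison and 2-sided tests. An adjusted p under 0.05 counted as a change, and rose, higher, fell and lower refer to that test. The comparisons were each dose against vehicle at each time, 3000 µM against 300 µM at each time, vehicle at 48 h against 24 h, and the difference of each dose's effect between 48 h and 24 h.

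The groups, the comparisons, the filter, the 35 gene lists, the rule for naming genes and all alternatives but the last were chosen before the data were examined. The lists cover CAR/PXR phase I enzymes (targets of the constitutive androstane and pregnane X receptors), phase II conjugation, drug and bile acid transporters, AhR targets, Nrf2 targets, PPARalpha targets and fatty acid oxidation, cholesterol biosynthesis and SREBP2 targets, and lipogenesis. They also cover bile acid synthesis, gluconeogenesis and glycolysis, hepatocyte secreted and identity genes, urea cycle and amino acid catabolism, acute phase and complement, cytokines and NF-kB targets, interferon response, cell cycle, and p53 and DNA damage. Further lists hold the integrated stress response, the unfolded protein response, heat shock, heme and iron, pericentral and beta-catenin targets, periportal genes, nuclear receptors and cofactors, circadian clock, and male-predominant or growth hormone regulated genes. The others are the mitochondrial respiratory chain, proteasome, cytosolic ribosomal proteins, cytoskeleton and dedifferentiation, and markers of stellate cells and fibroblasts, macrophages, endothelial cells, cholangiocytes and lymphocytes. Lists had 10 to 46 members and share some members.

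Each list was tested on a table with 1 probe set per gene, the probe set with the highest mean, by limma's camera with a preset inter-gene correlation of 0.01. Camera asks whether a list's members shift relative to the other genes, and was repeated with a correlation estimated for each list. List tests were planned for all comparisons but that of the vehicle groups, for which they were added. fry asks whether a list's members move, on balance, to 1 side and compares them with no other genes. Member counts are over all probe sets tested, and most are given also adjusted over the list alone.

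Genes are named by a fixed rule. In each comparison of a dose with vehicle these are the 10 largest rises and the 10 largest falls among genes with 1 symbol that passed the test and had all 5 treated arrays on 1 side of all 5 vehicle arrays, up to 4 changed members with the largest fold of each list, and always Cyp2b1, Cyp2b2 and Cyp3a23-3a1. Transcripts known by a locus identifier alone were counted and not named. Cyp2b1 and Cyp2b2 are read by a probe set that carries both symbols, so that neither can be given alone and neither entered a list count.

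The code was tested on simulated data in which 50 of 16596 probe sets were changed per fold: 28% of 1.25-fold, 64% of 1.5-fold, 96% of 2-fold and 96% of 4-fold changes were recovered, with 3 false calls. The alternatives were quantile normalization, array median centring, added constants of 16 and 64, no filter, a filter at the 75th percentile, fits with the compared groups alone, sets of 6 in the running number of the titles as a block, that number as a covariate, eBayes without trend and robust estimation, array weights, the mean of a gene's probe sets, camera with an estimated correlation, fry, a vehicle group split into 2 and 3 arrays, and leaving out each array. A fit without the 2 arrays that stood apart in quality measures was added after the data were seen. For each comparison, 100 splits of the arrays, the real one among them, were drawn with seed 1. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The 57 controls were kept out of the tests, and some served as quality measures.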

Results

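The data were 30 arrays of cultured rat hepatocytes in 6 groups of 5 wells: vehicle, 300 µM and 3000 µM phenobarbital, each at 24 h and 48 h after dosing. Phenobarbital is a barbiturate used against seizures and is widely used in toxicology as an inducer of liver drug metabolism through CAR, with part of the response through PXR. Each array's median signal was between 349 and 424.9. Across probe sets, arrays of the same group correlated with r between 0.951 and 0.982, and the first principal component held 27.8% of the variance. Array 1 of the 24 h vehicle group and array 4 of the 48 h group at 3000 µM stood apart in their hybridization controls.

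**Figure D1:**
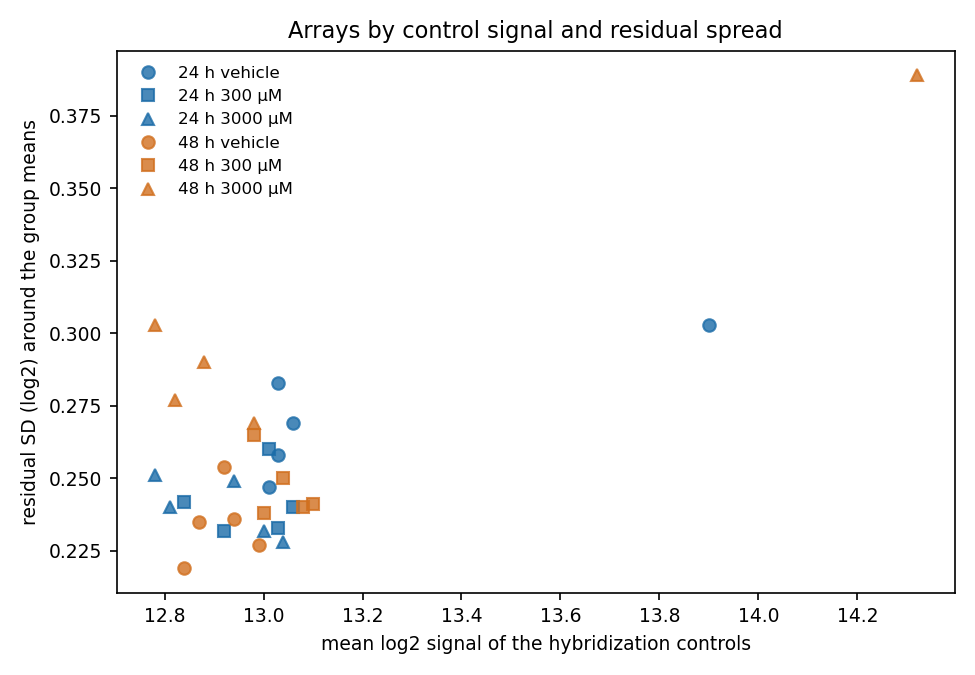
Mean log2 signal of 9 hybridization control probe sets against the residual standard deviation of each of the 30 arrays, with symbols for dose and time. Array 1 of the 24 h vehicle group and array 4 of the 48 h group at 3000 µM had the highest control signals, 13.90 and 14.32, and residual standard deviations of 0.303 and 0.389.

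At 300 µM few probe sets changed, and the one shared by Cyp2b1 and Cyp2b2 rose most. It was far lower at 3000 µM than at 300 µM. At 3000 µM 32% of probe sets changed at 24 h and 39.4% at 48 h. At both times the integrated stress response list shifted higher and the list of PPARalpha targets lower in both forms of the list test. Lists of bile acid synthesis, glucose metabolism and amino acid breakdown genes also shifted lower at both times, but with an estimated correlation this was lost at 48 h (adjusted p 0.12, 0.202 and 0.202). The list of cholesterol biosynthesis and SREBP2 targets shifted higher with the preset correlation alone (0.0521 and 0.414 with an estimated one).

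**Figure D2:**
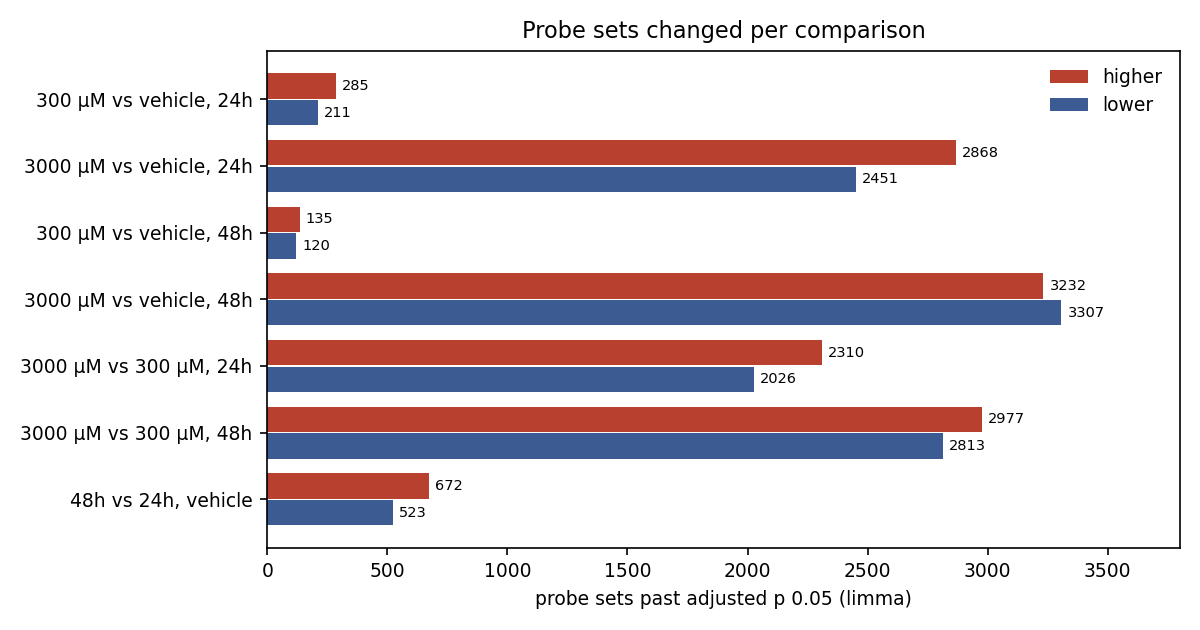
Number of probe sets higher and lower in 7 comparisons of groups of 5 arrays, of 16596 tested with limma. The 300 µM comparisons gave 496 and 255 changed probe sets at 24 h and 48 h, and the 3000 µM comparisons gave 5319 and 6539.

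The comparison of 300 µM with vehicle at 24 h asked which genes respond first to the lower dose. The probe set shared by Cyp2b1 and Cyp2b2 rose most. Meox2, Cyp2c6v1 and Cyp7a1, whose enzyme starts the main route from cholesterol to bile acids, were among the other large rises. The list of PPARalpha targets, which serve fatty acid oxidation, shifted lower, with 7 of 30 members past the test. Changes were few: 496 of 16596 probe sets changed, 285 higher and 211 lower. By at least 2-fold, 18 were higher and 3 lower.

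The probe set shared by Cyp2b1 and Cyp2b2, the classic phenobarbital-induced P450 genes of rat liver, rose 24.3-fold (log2 change 4.61, limma adjusted p 1.73e-14). Its log2 signal went from 10.57 ± 0.0802 to 15.17 ± 0.127 (mean ± SD, n = 5 arrays each). Cyp2c6v1, another P450 of drug metabolism, rose 4.11-fold, from 13.89 ± 0.0457 to 15.93 ± 0.0503 (n = 5 each, limma adjusted p 1.68e-23). Cyp7a1 rose 3.51-fold (log2 change 1.81, SE 0.246, adjusted p 2.05e-05). The other large rises were the homeobox gene Meox2 (2.61, SE 0.645, from a vehicle signal below the filter's level), the receptor kinase gene Grk5 (1.30), Tsku (1.19), and the lysine-degrading enzyme gene Aass (1.08). The chemokine gene Cxcl9 (0.97), the ceramide synthase gene Cers6 (0.96), the oxysterol hydroxylase gene Cyp39a1 (0.95) and the estrogen sulfotransferase gene Sult1e1 (0.86) followed. Falls were smaller and led by Rprm (-1.11, SE 0.263), Eva1c (-0.87), the matrix protein gene Ccn2 (-0.86) and Tnk2 (-0.78). Hsd17b13 (-0.65), Cyp2e1 (-0.64), Diaph3 (-0.63), Cyp4a1 (-0.61), B3galnt1 (-0.60) and Magee1 (-0.59) also fell. Cyp3a23-3a1, another usual target, was at 0.034 (adjusted p 0.944). Its vehicle signal (16.25 ± 0.186) was near the top of the scale, which may hide rises.

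Of 15 measured CAR/PXR phase I enzymes, 6 rose and 9 did not pass (9 rose adjusted over the list alone). Besides Cyp2c6v1 the heme synthesis gene Alas1 (0.76), Cyp3a2 (0.68) and Cyp2c7 (0.58) rose, and the list's shift held in both forms of the test (camera adjusted p 5.42e-14, and 0.00121 with an estimated correlation). Of 29 phase II conjugation genes, 5 rose, 1 fell and 23 did not pass (5 rose and 3 fell adjusted over the list alone). Sult1e1, Gstt3 (0.86), Gsta4 (0.37) and Gstk1 (0.37) rose without a shift of the list (camera adjusted p 0.253). Of 18 drug and bile acid transporters, 3 rose, 1 fell and 14 did not pass (4 rose and 2 fell adjusted over the list alone). The efflux pump genes Abcb1a (0.70), Abcc3 (0.36) and Abcb11 (0.21) rose and the uptake carrier gene Slco1a1 (-0.41) fell (camera adjusted p 0.063). Of 25 Nrf2 targets, which answer oxidative stress, 6 rose and 19 did not pass (12 rose and 2 fell adjusted over the list alone). Slc7a11 (0.49), Hmox1 (0.46), Gclc (0.40) and Me1 (0.34) rose most (camera adjusted p 7.9e-05, and 0.116 with an estimated correlation). Of 17 heme and iron genes, 4 rose, 1 fell and 12 did not pass (4 rose and 1 fell adjusted over the list alone). Alas1, Hmox1 and Uros (0.43) rose and Fech (-0.30) fell (camera adjusted p 0.0407, and 0.116 with an estimated correlation). Of 14 male-predominant or growth hormone regulated genes, 4 rose and 10 did not pass (4 rose and 2 fell adjusted over the list alone). Sult1e1, Cyp3a2, Cyp2c7 and Cyp2c11 (0.30) rose (camera adjusted p 0.027, and 0.223 with an estimated correlation).

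Of 30 PPARalpha targets and fatty acid oxidation genes, 7 fell and 23 did not pass (10 fell adjusted over the list alone). Cyp4a1, Angptl4 (-0.53), Cyp4a3 (-0.45) and Acadm (-0.30) fell most, and the shift held in both forms of the test (camera adjusted p 1.82e-10, and 0.0182 with an estimated correlation). Of 13 periportal genes, normally highest where blood enters the liver lobule, 2 fell and 11 did not pass (6 fell adjusted over the list alone). Hsd17b13 and Pigr (-0.37) fell, and the list shifted lower (camera adjusted p 7.95e-06, and 0.0186 with an estimated correlation). Of 23 cholesterol biosynthesis and SREBP2 targets, 5 rose and 18 did not pass (10 rose adjusted over the list alone). This list moved the other way, with the fatty acid desaturase gene Fads1 (0.52) and the sterol synthesis genes Msmo1 (0.44), Mvd (0.41) and Idi1 (0.39) as the largest rises (camera adjusted p 1.44e-07, and 0.104 with an estimated correlation). Of 14 bile acid synthesis genes, 2 rose, 1 fell and 11 did not pass (2 rose and 4 fell adjusted over the list alone). Cyp7a1 and Acox2 (0.73) rose and Slc27a2 (-0.34) fell, and the median (-0.11) and the test pointed lower and the mean (0.041) higher (camera adjusted p 0.34). The integrated stress response is a program of amino acid shortage and translation control. Of 28 genes of this program, 3 rose, 1 fell and 24 did not pass (6 rose and 1 fell adjusted over the list alone). Slc7a11 (0.49), Psat1 (0.30) and Psph (0.22) rose and Nupr1 (-0.21) fell (camera adjusted p 5.76e-05, and 0.09 with an estimated correlation).

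Several lists shifted lower with few members past the test, and none of these kept its call with an estimated correlation. Among 31 hepatocyte secreted and identity genes, Apoa5 (-0.37), Tdo2 (-0.32) and Ambp (-0.24) fell (adjusted p = 0.116 with an estimated correlation). Pfkfb1 (-0.30) fell in gluconeogenesis and glycolysis (0.116), Tdo2 in urea cycle and amino acid catabolism (0.104) and Cyp2e1 among pericentral genes (0.116). Ccn2, Vim (-0.36), Fn1 (-0.29) and Krt18 (-0.26) fell in cytoskeleton and dedifferentiation (0.138). Mitochondrial respiratory chain (0.116) and macrophage markers (0.116) shifted lower without a member past the test. The proteasome list shifted higher with Psmc4 (0.25) alone past the test (0.116). Cytosolic ribosomal proteins shifted lower by a median of -0.15 with Rps9 (-0.23) past the test (0.223 with an estimated correlation), a shift that ended under quantile normalization (median -0.0049, adjusted p 0.644).

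With array medians centred, 227 probe sets changed in place of 496, and without array 2 or array 4 at 300 µM 325 and 326 did. Meox2 lost its call without array 2 at 300 µM (adjusted p 0.0542) or vehicle array 4 (0.0688) or 5 (0.0719), Rprm without vehicle array 2 (0.0512), and Eva1c in 4 settings, among them without vehicle array 1 or array 3 at 300 µM (up to 0.125), against lowest values over the alternatives of 0.00289, 0.00255 and 0.002.

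**Figure D3:**
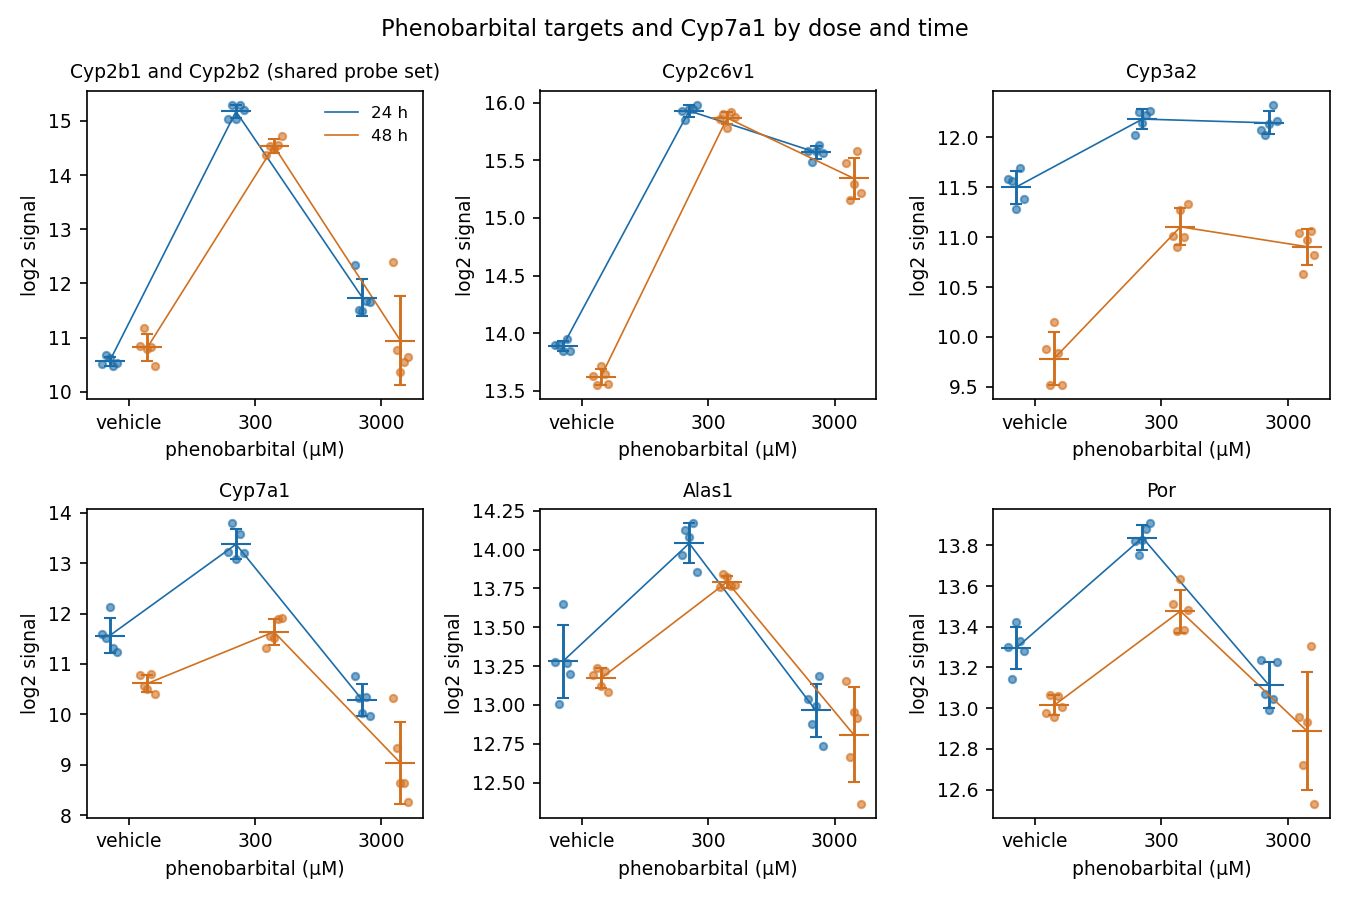
Log2 signal of the probe set shared by Cyp2b1 and Cyp2b2 and of Cyp2c6v1, Cyp3a2, Cyp7a1, Alas1 and Por on each array, by dose and time, with the mean and SD of 5 arrays. The shared probe set was at 15.17 at 300 µM and 11.74 at 3000 µM after 24 h, against 10.57 in vehicle.

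The comparison of 300 µM with vehicle at 48 h asked how the lower dose's response stood a day later. The shared Cyp2b1 and Cyp2b2 probe set and Cyp2c6v1 again rose, and Cyp3a2 joined the largest rises. The phase II conjugation and Nrf2 lists shifted higher, with 5 of 29 and 5 of 25 members past the test, and PPARalpha targets lower, with 5 of 30. In all, 255 probe sets changed, 135 higher and 120 lower, 12 of them by at least 2-fold (7 higher and 5 lower).

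The shared Cyp2b1 and Cyp2b2 probe set rose 13.1-fold, from 10.82 ± 0.251 to 14.53 ± 0.131 (n = 5 each, limma adjusted p 3.36e-12). Cyp2c6v1 rose 4.75-fold (log2 change 2.25, SE 0.0562, adjusted p 7.85e-25). Cyp3a2, a testosterone-hydroxylating P450, rose 2.5-fold (1.32, SE 0.107, adjusted p 3.95e-10). Other rises were Grk5 (1.33), Cyp7a1 (1.02), Cxcl9 (0.9952) and Srpx (0.97), the aromatic amino acid decarboxylase gene Ddc (0.97), Cym (0.96), Uggt1 (0.95) and Tsku (0.94). The carboxylesterase gene Ces1d fell most (-1.14, SE 0.102, adjusted p 2.31e-09). Plekhm2 (-1.11), Cyp4a1 (-0.85), Acsm3 (-0.81), Txnip (-0.68), Akr1c1 (-0.68), Slco1a1 (-0.64), Cd209f (-0.63), Ccn2 (-0.63) and Klf11 (-0.62) followed. Cyp3a23-3a1 was at 0.25 (adjusted p 0.368).

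Of 15 CAR/PXR phase I enzymes, 7 rose and 8 did not pass (10 rose adjusted over the list alone). Alas1 (0.62) and the P450 reductase gene Por (0.46) were among them, and the shift held in both forms of the test (camera adjusted p 1.53e-21, and 5.73e-05 with an estimated correlation). Of 29 phase II conjugation genes, 5 rose and 24 did not pass (10 rose and 1 fell adjusted over the list alone). Gstt3 (0.84), Gsta4 (0.63), Ugt2b1 (0.56) and Sult1e1 (0.54) rose most (camera adjusted p 9.97e-09, and 0.00984 with an estimated correlation). Of 25 Nrf2 targets, 5 rose and 20 did not pass (15 rose adjusted over the list alone). Hmox1 (0.43), Gsr (0.36), Srxn1 (0.31) and Nqo1 (0.24) rose most (camera adjusted p 1.22e-14, and 0.00556 with an estimated correlation). Of 17 heme and iron genes, 3 rose and 14 did not pass (3 rose adjusted over the list alone). Alas1, Hmox1 and Blvrb (0.39) rose (camera adjusted p 0.006, and 0.0489 with an estimated correlation). Of 30 proteasome genes, 3 rose and 27 did not pass (9 rose adjusted over the list alone). Psmb5 (0.26), Psmc5 (0.20) and Psmc4 (0.19) rose (camera adjusted p 3.38e-10, and 0.0175 with an estimated correlation). Of 28 integrated stress response genes, 1 rose and 27 did not pass (3 rose adjusted over the list alone). Psat1 (0.33) was the member that rose (camera adjusted p 1.71e-05, and 0.0372 with an estimated correlation). Of 30 PPARalpha targets and fatty acid oxidation genes, 5 fell and 25 did not pass (14 fell adjusted over the list alone). Cyp4a1 (-0.85), Angptl4 (-0.55), Cyp4a3 (-0.52) and Pdk4 (-0.37) fell most (camera adjusted p 6.09e-13, and 0.00556 with an estimated correlation).

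Of 14 bile acid synthesis genes, 2 rose, 2 fell and 10 did not pass (2 rose and 3 fell adjusted over the list alone). Cyp7a1 and Acox2 (0.92) rose and Slc27a5 (-0.43) and Slc27a2 (-0.33) fell (camera adjusted p 0.427). Of 14 male-predominant or growth hormone regulated genes, 4 rose, 1 fell and 9 did not pass (4 rose and 1 fell adjusted over the list alone). Cyp3a2, Cyp2c11 (0.57) and Sult1e1 (0.54) rose and Ghr (-0.50) fell (camera adjusted p 0.00259, and 0.123 with an estimated correlation). Of 6 AhR targets Nqo1 rose (camera adjusted p 0.0108, and 0.116 with an estimated correlation). Of 18 interferon response genes Isg15 (-1.02) fell (camera adjusted p 0.0342, and 0.529 with an estimated correlation). Its vehicle array 5 was at 12.09, the others averaging 10.67. In acute phase and complement, Crp (0.55), Lcn2 (0.28) and Mbl2 (0.21) rose and Lbp (-0.36) fell without a shift of the list (0.461), and among transporters Abcc2 (0.29) rose and Slco1a1 fell (0.948). Single members passed in lists without a shift: Abca1 (-0.28) in lipogenesis (0.445), Pfkfb1 (-0.26) in glucose metabolism (0.105) and Cdh1 (-0.33) among periportal genes (0.242). Nr2f2 (-0.28) fell among nuclear receptors (0.791) and Ggt1 (0.43) rose among cholangiocyte markers (0.791). Mitochondrial respiratory chain and cytosolic ribosomal protein lists shifted higher (0.0182 and 0.00382) with no member past the test. Both calls ended under quantile normalization and with an estimated correlation (0.642 and 0.646).

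The count at 48 h moved with the setting: 482 probe sets changed with the compared groups alone in the fit, 467 without the 2 arrays that stood apart, 615 with array weights, 124 with array medians centred (83 higher and 41 lower) and 168 without vehicle array 4. Cyp7a1 lost its call in 5 of 23 settings, without vehicle arrays 3 or 5, without 300 µM arrays 4 or 5, and with medians centred (adjusted p 0.0582 to 0.0742, lowest over the alternatives 4.95e-05), and Plekhm2, Acsm3 and Cd209f lost theirs in 9, 9 and 10 settings, 6, 7 and 7 of which left out 1 array (up to 0.115, 0.0786 and 0.106, from lowest values of 0.0124, 0.00629 and 0.000673).

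The comparison of 3000 µM with vehicle at 24 h asked what the higher dose did. The integrated stress response list shifted higher, and lists of PPARalpha target, bile acid synthesis, glucose metabolism and amino acid breakdown genes shifted lower, in both forms of the test. With the preset correlation alone, the list of cholesterol biosynthesis and SREBP2 targets shifted higher and the hepatocyte secreted and acute phase lists lower (adjusted p 0.0521, 0.0512 and 0.0512 with an estimated one). The gene of the nuclear receptor CAR (Nr1i3), through which phenobarbital acts, fell. In all, 5319 probe sets changed, 32% of those tested, 2868 higher and 2451 lower. By at least 2-fold 439 changed, 155 higher and 284 lower (191 and 231 with array medians centred).

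The thrombomodulin gene Thbd had the largest rise, from 5.76 ± 1.37 to 10.78 ± 0.357 (n = 5 each, limma adjusted p 2.93e-09). Its vehicle signal was below the filter's level of 384, so that no fold is given, and its other probe set rose by 3.74 on the log2 scale. Other rises from below that level, so imprecise, were Tnfrsf1b (3.06), Rgs19 (2.13), Igsf23 (1.99), Mtrf1 (1.94), Miga1 (1.84), Opn3 (1.74) and Nfe2 (1.69). Stmn1 (1.74) and Shc4 (1.71) also rose. Cyp8b1, which sets the cholic acid share of bile acids, fell 11.3-fold (-3.504, SE 0.194, adjusted p 8.22e-15). Clec14a (-3.93), Rprm (-2.76, to below the filter's level), Poteml2 (-2.54), Txnip (-2.44) and Cyp17a1 (-2.38) also fell strongly. Rem2 (-2.34), the muscle actin gene Acta1 (-2.34), the lipid droplet gene Plin5 (-2.29) and Abcc9 (-2.25) followed. Clec14a was near the bottom of the scale in treated wells (5.33 ± 1.86). The shared Cyp2b1 and Cyp2b2 probe set rose 2.25-fold to 11.74 ± 0.344 (n = 5, limma adjusted p 0.000166), and by 1.02 on the log2 scale without array 1 at 3000 µM. Cyp3a23-3a1 was at 0.017 (adjusted p 0.935).

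Of 28 integrated stress response genes, 20 rose, 3 fell and 5 did not pass (21 rose and 3 fell adjusted over the list alone). Gdf15 (1.30), Ddit3 (1.29), Slc7a5 (1.18) and Atf3 (1.11) rose most, and the shift held in both forms of the test (camera adjusted p 7.34e-10, and 0.00584 with an estimated correlation). Of 17 p53 and DNA damage genes, 10 rose, 3 fell and 4 did not pass (10 rose and 3 fell adjusted over the list alone). Gdf15 (1.30), Mdm2 (1.02) and Plk2 (0.81) rose and Sesn1 (-1.02) fell (camera adjusted p 0.00684, and 0.068 with an estimated correlation). Of 23 cholesterol biosynthesis and SREBP2 targets, 15 rose, 1 fell and 7 did not pass (17 rose and 1 fell adjusted over the list alone). Msmo1 (1.21), Cyp51 (1.07), Mvd (0.98) and Idi1 (0.95) rose most (camera adjusted p 3.73e-08, and 0.0521 with an estimated correlation). Of 30 proteasome genes, 16 rose, 2 fell and 12 did not pass (17 rose and 2 fell adjusted over the list alone). Psmd11 (0.48), Psmd2 (0.43), Psmc4 (0.42) and Psmd4 (0.37) rose most (camera adjusted p 0.000679, and 0.181 with an estimated correlation). Of 24 unfolded protein response genes, 9 rose, 4 fell and 11 did not pass (10 rose and 7 fell adjusted over the list alone). Sdf2l1 (0.77), Atf6 (0.59) and Dnajb9 (0.48) rose and Edem1 (-0.58) fell without a shift of the list (camera adjusted p 0.186). Of 18 heat shock genes, 9 rose, 2 fell and 7 did not pass (9 rose and 2 fell adjusted over the list alone). Hsph1 (0.68) and Hspa4l (0.48) rose and Cryab (-0.87) and Hspa1a (-0.57) fell (camera adjusted p 0.327).

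Of 30 PPARalpha targets and fatty acid oxidation genes, 1 rose, 24 fell and 5 did not pass (1 rose and 24 fell adjusted over the list alone). The carnitine palmitoyltransferase gene Cpt1a (-1.54), Cyp4a1 (-1.49) and Angptl4 (-1.17) fell, and the shift held in both forms of the test (camera adjusted p 1.16e-16, and 0.00258 with an estimated correlation). Of 14 bile acid synthesis genes, 11 fell and 3 did not pass (11 fell adjusted over the list alone). Cyp8b1, Cyp7a1 (-1.28), Nr1h4 (-0.90) and Baat (-0.66) fell most (camera adjusted p 4.63e-08, and 0.0302 with an estimated correlation). Of 22 gluconeogenesis and glycolysis genes, 14 fell and 8 did not pass (2 rose and 15 fell adjusted over the list alone). Gys2 (-1.67), Pklr (-1.33), Pc (-1.30) and Pfkfb1 (-0.81) fell most (camera adjusted p 1.13e-07, and 0.0302 with an estimated correlation). Of 32 genes of the urea cycle and amino acid catabolism, 1 rose, 19 fell and 12 did not pass (3 rose and 19 fell adjusted over the list alone). Bhmt (-1.53), Sardh (-1.31), Gnmt (-1.20) and Agxt (-1.18) fell most (camera adjusted p 8.76e-07, and 0.0195 with an estimated correlation). Of 13 periportal genes, 10 fell and 3 did not pass (10 fell adjusted over the list alone). Hsd17b13 (-1.40), Fbp1 (-0.75), Pck1 (-0.70) and Cyp2f4 (-0.61) fell most (camera adjusted p 8.21e-05, and 0.0302 with an estimated correlation). Of 16 pericentral and beta-catenin targets, 1 rose, 8 fell and 7 did not pass (1 rose and 9 fell adjusted over the list alone). Cyp2e1 (-0.78), Gulo (-0.65), Nt5e (-0.65) and Cyp1a2 (-0.48) fell (camera adjusted p 0.000424, and 0.0375 with an estimated correlation). Of 31 hepatocyte secreted and identity genes, 1 rose, 23 fell and 7 did not pass (1 rose and 26 fell adjusted over the list alone). Foxa1 (-1.55), Plg (-0.83), F10 (-0.72) and Prox1 (-0.59) fell most (camera adjusted p 3.06e-10, and 0.0512 with an estimated correlation). The actin 3'/5' log2 ratio, a measure of RNA integrity, was 1.55 against 1.51 in vehicle (exact permutation p 0.437, n = 5 each). Of 34 acute phase and complement genes, 3 rose, 24 fell and 7 did not pass (3 rose and 26 fell adjusted over the list alone). C5 (-1.08), Serpina3n (-0.96) and Il6r (-0.95) fell and Il1r1 (0.94) rose (camera adjusted p 3.02e-08, and 0.0512 with an estimated correlation).

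Drug metabolism genes were mixed at this dose. Of 15 CAR/PXR phase I enzymes, 5 rose, 3 fell and 7 did not pass (5 rose and 3 fell adjusted over the list alone). Cyp2c6v1 (1.68) and Cyp3a2 (0.64) rose and Cyp2a1 (-0.80) and Cyp2a2 (-0.41) fell without a shift of the list (camera adjusted p 0.428). Of 29 phase II conjugation genes, 7 rose, 11 fell and 11 did not pass (7 rose and 13 fell adjusted over the list alone). Sult1c2 (1.69) and Gstk1 (1.44) rose and Nat1 (-0.76) and Gstm7 (-0.68) fell (camera adjusted p 0.346). Of 18 drug and bile acid transporters, 7 rose, 7 fell and 4 did not pass (7 rose and 7 fell adjusted over the list alone). The bile acid uptake carrier gene Slc10a1 (-1.41) and Slco1b2 (-0.91) fell and Abcb1a (1.28) and Slco1a4 (0.97) rose (camera adjusted p 0.932). Of 25 Nrf2 targets, 7 rose, 7 fell and 11 did not pass (8 rose and 7 fell adjusted over the list alone). Trib3 (0.93) and Slc7a11 (0.48) rose and Akr1b8 (-0.72) and Cbr1 (-0.41) fell, with a median of -0.02, a mean of 0.020 and a test pointing lower (camera adjusted p 0.815). Of 20 nuclear receptors and cofactors, 1 rose, 8 fell and 11 did not pass (1 rose and 8 fell adjusted over the list alone). Nr1i3 (-1.39), Nr1h4 (-0.90), Nr5a2 (-0.53) and Nr1i2 (-0.38) fell (camera adjusted p 0.0275, and 0.16 with an estimated correlation). Of 23 lipogenesis genes, 5 rose, 8 fell and 10 did not pass (5 rose and 8 fell adjusted over the list alone). Lpin1 (-1.59), Thrsp (-1.30) and Acaca (-0.9991) fell and Aacs (1.10) rose (camera adjusted p 0.038, and 0.429 with an estimated correlation). Of 17 heme and iron genes, 3 rose, 5 fell and 9 did not pass (3 rose and 5 fell adjusted over the list alone). Hamp (-0.77) and Fech (-0.45) fell and Uros (0.39) and Hmox1 (0.35) rose (camera adjusted p 0.373). Of 14 male-predominant or growth hormone regulated genes, 3 rose, 7 fell and 4 did not pass (5 rose and 7 fell adjusted over the list alone). Bcl6 (-1.005), Igf1 (-0.87) and Ghr (-0.68) fell and Sult1e1 (0.65) rose (camera adjusted p 0.188).

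Of 28 mitochondrial respiratory chain genes, 19 fell and 9 did not pass (19 fell adjusted over the list alone). Atp5f1b (-0.29), Ndufv1 (-0.27), Uqcrc1 (-0.24) and Cox4i1 (-0.24) fell most, all by small steps (camera adjusted p 2.96e-06, and 0.16 with an estimated correlation). Of 27 cytoskeleton and dedifferentiation genes, 4 rose, 13 fell and 10 did not pass (5 rose and 14 fell adjusted over the list alone). Anxa1 (-1.42), Vim (-1.08), Ccn2 (-1.004) and Tgfb2 (-0.81) fell, Tgfb2 by 0.48 (adjusted p 0.0373) without array 3 at 3000 µM, and under quantile normalization the list's adjusted p of 0.175 ended its call (camera adjusted p 0.0275, and 0.407 with an estimated correlation). Of 22 cytosolic ribosomal protein genes, Rpl3 (-0.18), Rps16 (-0.16), Rps9 (-0.16) and Rps15 (-0.15) fell (no member passed adjusted over the list alone) and the list shifted lower (-0.11, camera adjusted p 0.0275, and 0.669 with an estimated correlation), but under quantile normalization the list's median was 0.068 (adjusted p 0.0971) and Rpl3 was at 0.025 (0.491). Markers of other cell types did not rise together. Of 12 stellate and fibroblast markers, 3 fell and 9 did not pass (3 fell adjusted over the list alone). Lox (-1.51), Sparc (-0.70) and Rgs5 (-0.43) fell (camera adjusted p 0.0872). Of 13 macrophage markers, 2 rose, 5 fell and 6 did not pass (2 rose and 5 fell adjusted over the list alone). C1qb (-1.62), C1qa (-0.81) and Ctss (-0.77) fell and Cd68 (0.54) rose (camera adjusted p 0.107).

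With array medians centred, 3403 probe sets were higher and 1680 lower, so the balance of directions depended on the scaling. Igsf23 lost its call in 10 of 22 settings, among them without vehicle array 1, 2, 3, 4 or 5 or array 3 or 5 at 3000 µM (adjusted p up to 0.276, lowest 0.00658), and Opn3 without vehicle array 2 (0.0723) or array 4 at 3000 µM (0.0512), from a lowest value of 0.00198.

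The comparison of 3000 µM with vehicle at 48 h asked whether the high-dose response was there a day later. The integrated stress response list was again higher and the list of PPARalpha targets lower in both forms of the test. The proteasome list was higher, and lists of bile acid synthesis, glucose metabolism, amino acid breakdown and hepatocyte secreted genes lower, with the preset correlation alone (adjusted p 0.127, 0.12, 0.202, 0.202 and 0.204 with an estimated one). The probe set shared by Cyp2b1 and Cyp2b2 did not pass the test against vehicle. Of 16596 probe sets, 6539 changed (39.4%), 3232 higher and 3307 lower, and 699 reached 2-fold, 211 higher and 488 lower.

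Thbd again rose, from 6.36 ± 0.539 to 11.81 ± 0.185 (n = 5 each, limma adjusted p 2.65e-10), its vehicle signal again below the filter's level and its other probe set at 4.25. Arhgap22 (4.31), Rsad2 (2.46) and, from below that level, Igsf23 (3.71) and Rgs19 (2.37) were other large rises. Ddit3, which encodes the stress transcription factor CHOP, rose 4.36-fold (log2 change 2.12, SE 0.0904, adjusted p 1.98e-18). Pla2g4b (2.06) and Mapk4 (1.89), from below the filter's level, Shc4 (1.91) and Gstk1 (1.82, SE 0.0691, adjusted p 7.04e-20) completed the largest rises. Clec14a, a surface protein gene known mainly from blood vessel lining, fell most (-6.58), from a mean signal of 1303 to 13.6, the latter too low to give the size of the fall. Acta1 (-3.40), Poteml2 (-3.30), Abcc9 (-3.01), Rem2 (-2.96), Cyp17a1 (-2.96), Cyp8b1 (-2.93) and Lmcd1 (-2.75) followed. Tmem255b (-3.004) and Calml4 (-2.74) fell to below the filter's level. The shared Cyp2b1 and Cyp2b2 probe set was at 10.95 ± 0.825 against 10.82 ± 0.251 in vehicle (log2 change 0.12, limma adjusted p 0.706, n = 5 each), and its change was -0.24 (0.144) without array 1 at 3000 µM. Cyp3a23-3a1 rose by 0.35 (adjusted p 0.0144, 0.000231 to 0.0927 over the alternatives, the highest with the compared groups alone in the fit), and by 0.16 (adjusted p 0.0304) without array 4 at 3000 µM.

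Of 28 integrated stress response genes, 21 rose, 3 fell and 4 did not pass (21 rose and 4 fell adjusted over the list alone). Ddit3, Gdf15 (1.42), Sesn2 (1.23) and Atf3 (1.19) rose most (camera adjusted p 2.39e-07, and 0.0234 with an estimated correlation). Of 17 p53 and DNA damage genes, 10 rose, 2 fell and 5 did not pass (10 rose and 2 fell adjusted over the list alone). Plk2 (1.04) and Mdm2 (1.02) rose with Gdf15 and Sesn2 (camera adjusted p 0.00483, and 0.127 with an estimated correlation). Of 24 unfolded protein response genes, 12 rose, 2 fell and 10 did not pass (12 rose and 3 fell adjusted over the list alone). Sdf2l1 (1.35), Atf6 (0.72) and Calr (0.51) rose, Calr by 0.30 (adjusted p 0.000166) without array 4 at 3000 µM, and Edem1 (-0.82) fell (camera adjusted p 0.00651, and 0.202 with an estimated correlation). Of 30 proteasome genes, 22 rose, 2 fell and 6 did not pass (23 rose and 2 fell adjusted over the list alone). Psma7 (0.56), Psmd11 (0.55), Psmd2 (0.53) and Psmc4 (0.46) rose most (camera adjusted p 7.55e-06, and 0.127 with an estimated correlation). Of 23 cholesterol biosynthesis and SREBP2 targets, 13 rose, 4 fell and 6 did not pass (13 rose and 4 fell adjusted over the list alone). Cyp51 (0.86), Msmo1 (0.86), Acat2 (0.81) and Sc5d (0.55) rose (camera adjusted p 0.0119, and 0.414 with an estimated correlation). Of 22 cytosolic ribosomal protein genes, 12 rose and 10 did not pass (14 rose adjusted over the list alone). Rpl14 (0.26), Rpl18 (0.22), Rpl19 (0.21) and Rps3 (0.21) rose most (camera adjusted p 0.00651, and 0.567 with an estimated correlation). Of 27 cell cycle genes, 13 rose, 1 fell and 13 did not pass (13 rose and 1 fell adjusted over the list alone). Ccne1 (1.43), Prc1 (1.22) and E2f1 (1.06) rose, though E2f1 was at 0.69 (adjusted p 0.175) without vehicle array 1 and Prc1 at 0.80 (adjusted p 0.201) without vehicle array 5, and Ccne2 (-1.05) fell. Camera called no shift of the list (adjusted p 0.0981), and fry did (2.18e-06). Of 18 interferon response genes, 5 rose, 7 fell and 6 did not pass (the same adjusted over the list alone). Rsad2, Psmb8 (1.13) and Psmb9 (0.98) rose and Isg15 (-1.18, vehicle array 5 again high) fell, and the median (-0.19) and test pointed lower and the mean (0.016) higher (camera adjusted p 0.923).

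Of 30 PPARalpha targets and fatty acid oxidation genes, 1 rose, 25 fell and 4 did not pass (1 rose and 25 fell adjusted over the list alone). Cyp4a1 (-2.13), Cpt1a (-1.74), Ehhadh (-1.48) and Fabp1 (-1.29) fell most (camera adjusted p 1.51e-14, and 0.00575 with an estimated correlation). Of 14 bile acid synthesis genes, 11 fell and 3 did not pass (11 fell adjusted over the list alone). Cyp8b1, Cyp7a1 (-1.57), Baat (-1.16) and Fgfr4 (-0.81) fell most (camera adjusted p 1.52e-06, and 0.12 with an estimated correlation). Of 22 gluconeogenesis and glycolysis genes, 9 fell and 13 did not pass (9 fell adjusted over the list alone). Gys2 (-1.97), Foxo1 (-1.69), Pc (-1.52) and Pklr (-1.34) fell most (camera adjusted p 0.000826, and 0.202 with an estimated correlation). Of 23 lipogenesis genes, 4 rose, 13 fell and 6 did not pass (4 rose and 14 fell adjusted over the list alone). Lpin1 (-1.76), Thrsp (-1.68), Scd2 (-1.49) and Acly (-0.98) fell most (camera adjusted p 0.00209, and 0.206 with an estimated correlation). Of 32 genes of the urea cycle and amino acid catabolism, 6 rose, 16 fell and 10 did not pass (9 rose and 17 fell adjusted over the list alone). Bhmt (-1.81), Gnmt (-1.60), Agxt (-1.53) and Gpt (-1.45) fell most (camera adjusted p 0.00651, and 0.202 with an estimated correlation). Of 31 hepatocyte secreted and identity genes, 1 rose, 17 fell and 13 did not pass (1 rose and 17 fell adjusted over the list alone). The transcription factor genes Foxa3 (-1.29), Onecut1 (-1.24) and Foxa1 (-1.13) and the plasminogen gene Plg (-1.23) fell most (camera adjusted p 1.68e-05, and 0.204 with an estimated correlation). The actin 3'/5' log2 ratio was 1.55 against 1.47 (exact permutation p 0.635, n = 5 each), and 1.91 on array 4. Of 34 acute phase and complement genes, 2 rose, 21 fell and 11 did not pass (2 rose and 22 fell adjusted over the list alone). Hamp (-1.80), C5 (-1.63), Serpina3n (-1.62) and Fga (-1.28) fell most (camera adjusted p 7.02e-07, and 0.127 with an estimated correlation). Of 13 periportal genes, 2 rose, 6 fell and 5 did not pass (2 rose and 6 fell adjusted over the list alone). Hsd17b13 (-1.45), Fbp1 (-0.97), Cdh1 (-0.81) and Cyp2f4 (-0.73) fell most (camera adjusted p 0.0285, and 0.204 with an estimated correlation). Of 16 pericentral and beta-catenin targets, 2 rose, 8 fell and 6 did not pass (2 rose and 9 fell adjusted over the list alone). Nt5e (-0.79), Gulo (-0.61) and Znrf3 (-0.51) fell and Rgn (1.004) rose (camera adjusted p 0.0285, and 0.204 with an estimated correlation).

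Drug metabolism was mixed at 48 h too. Of 15 CAR/PXR phase I enzymes, 7 rose, 3 fell and 5 did not pass (7 rose and 3 fell adjusted over the list alone). Cyp2c6v1 (1.73), Cyp3a2 (1.12) and Cyp3a18 (0.73) rose and Cyp2a1 (-1.14) fell (camera adjusted p 0.256). Of 29 phase II conjugation genes, 8 rose, 11 fell and 10 did not pass (9 rose and 12 fell adjusted over the list alone). Gstk1 and Sult1c2 (1.35) rose and Sult1c3 (-1.88) and Nat8 (-1.246) fell (camera adjusted p 0.894). Of 18 drug and bile acid transporters, 6 rose, 7 fell and 5 did not pass (6 rose and 8 fell adjusted over the list alone). Abcb1a (1.47) and Abcc2 (1.04) rose and Slc10a1 (-1.52) and Slco1b2 (-1.20) fell (camera adjusted p 0.894). Of 25 Nrf2 targets, 9 rose, 6 fell and 10 did not pass (11 rose and 6 fell adjusted over the list alone). Trib3 (0.97) and Abcc1 (0.50, or 0.28 at adjusted p 0.229 without vehicle array 5) rose and Akr1b8 (-1.35) and Me1 (-0.53) fell (camera adjusted p 0.627). Of 20 nuclear receptors and cofactors, 1 rose, 8 fell and 11 did not pass (2 rose and 8 fell adjusted over the list alone). Nr1i3 (-1.31), Nr3c1 (-0.71) and Nr2f2 (-0.68) fell and Ahr (1.251) rose (camera adjusted p 0.0367, and 0.204 with an estimated correlation). Of 14 male-predominant or growth hormone regulated genes, 3 rose, 7 fell and 4 did not pass (4 rose and 7 fell adjusted over the list alone). Bcl6 (-1.43), Cyp2c12 (-1.41) and Igf1 (-1.21) fell and Cyp3a2 rose (camera adjusted p 0.0542). Of 27 cytoskeleton and dedifferentiation genes, 8 rose, 8 fell and 11 did not pass (8 rose and 8 fell adjusted over the list alone). Ccn2 (-1.34), Anxa1 (-1.16), Vim (-1.16) and S100a4 (-1.01) fell, and the median was 0.056, the mean -0.13, and the test pointed lower (camera adjusted p 0.789). Mapk4 lost its call without vehicle array 2 (log2 change 1.05, adjusted p 0.132) and with array weights (0.0638), from a lowest value of 0.00513.

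**Figure D4:**
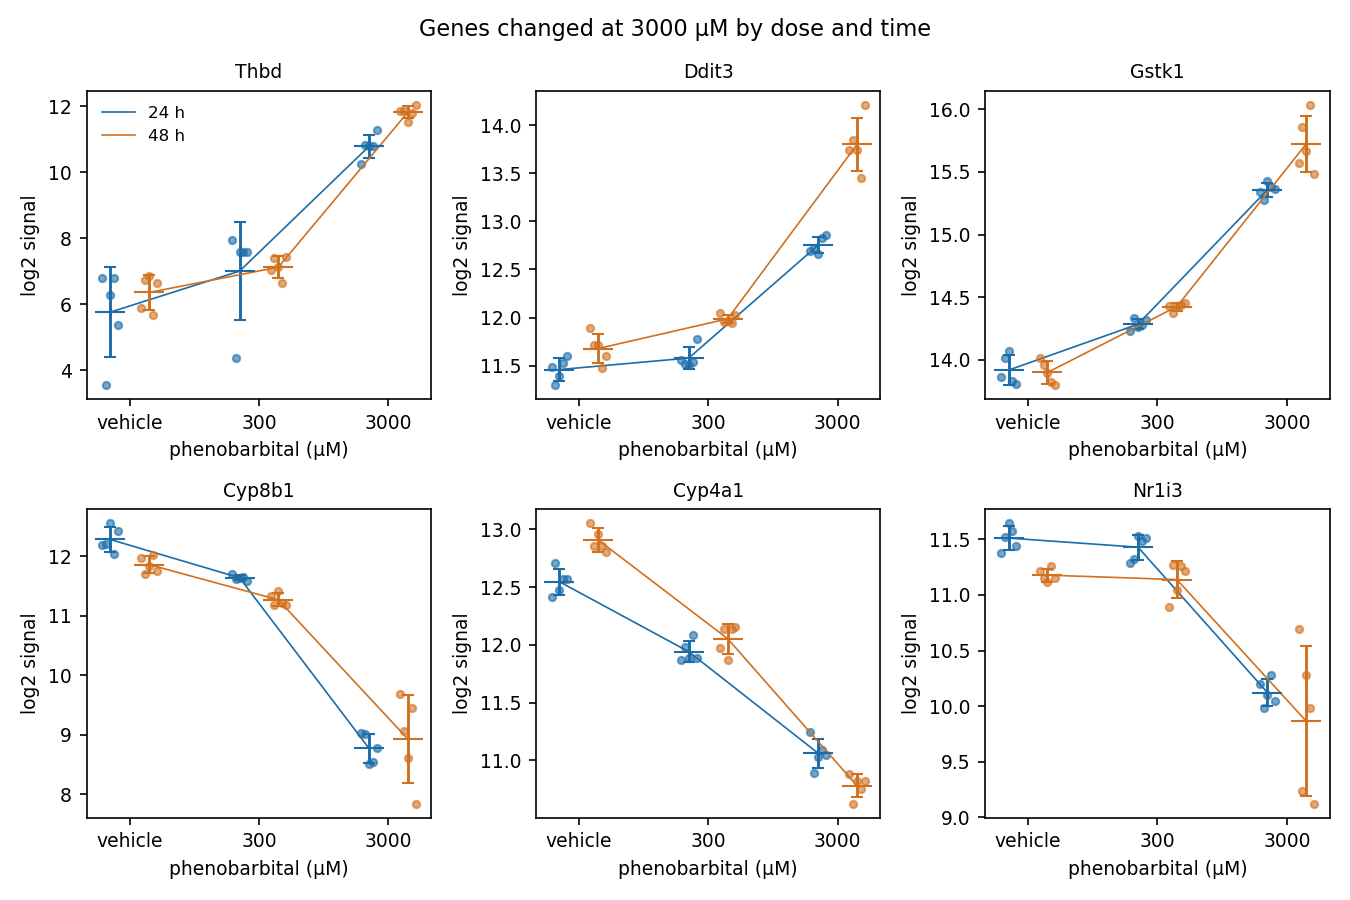
Log2 signal of Thbd, Ddit3, Gstk1, Cyp8b1, Cyp4a1 and Nr1i3 on each array, by dose and time, with the mean and SD of 5 arrays. Thbd rose from 5.76 to 10.78 at 3000 µM after 24 h, and from 6.36 to 11.81 after 48 h.

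The direct comparison of 3000 µM with 300 µM asked how the doses differ. Of the 8 phase I enzymes that rose at 300 µM, 5 were lower at 3000 µM than at 300 µM at both times. The integrated stress response list was higher, with 20 of 28 members higher and 3 lower at 24 h and 21 and 4 at 48 h (camera adjusted p 5.64e-08 and 1.2e-05), but with an estimated correlation the 48 h shift was lost (adjusted p 0.0176 and 0.0677). At 24 h 4336 probe sets differed, 2310 higher and 2026 lower at 3000 µM, with 68 higher and 206 lower by at least 2-fold. At 48 h 5790 differed, 2977 higher and 2813 lower, with 176 and 361 by at least 2-fold. The shared Cyp2b1 and Cyp2b2 probe set was 10.8-fold lower at 3000 µM at 24 h (log2 -3.43, adjusted p 3.97e-12) and 12-fold lower at 48 h (-3.58, adjusted p 5.04e-13). All 10 arrays at 300 µM were at or above 14.36 and all 10 at 3000 µM at or below 12.40. Cyp7a1 differed by -3.09 and -2.60, Alas1 by -1.07 and -0.98, and Cyp2c6v1 by -0.36 and -0.52, the last still above vehicle. Thbd was higher by 3.78 and 4.69, Ddit3 by 1.81 at 48 h, and Cyp8b1 differed by -2.86 and -2.33.

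CAR/PXR phase I enzymes were lower at 3000 µM than at 300 µM in 6 of 15 members at 24 h and 7 at 48 h, and higher in 1 each time. Adjusted over the list alone, 1 rose and 6 fell at 24 h and 2 and 7 at 48 h. With an estimated correlation their adjusted p was 0.101 and 0.17. PPARalpha targets were lower in 21 and 22 of 30 (adjusted over the list alone, 24 fell at 24 h, and 2 rose and 22 fell at 48 h), and theirs was 0.0142 and 0.0311. With the preset correlation 19 lists differed at 24 h, 3 higher and 16 lower at 3000 µM, and 21 at 48 h, 5 and 16. With an estimated correlation 2 and 1 did. Over the 8 comparisons planned for the lists, 119 shifts were called with the preset correlation and 22 of them with an estimated correlation, so the other 97 rest on the preset value.

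**Figure D5:**
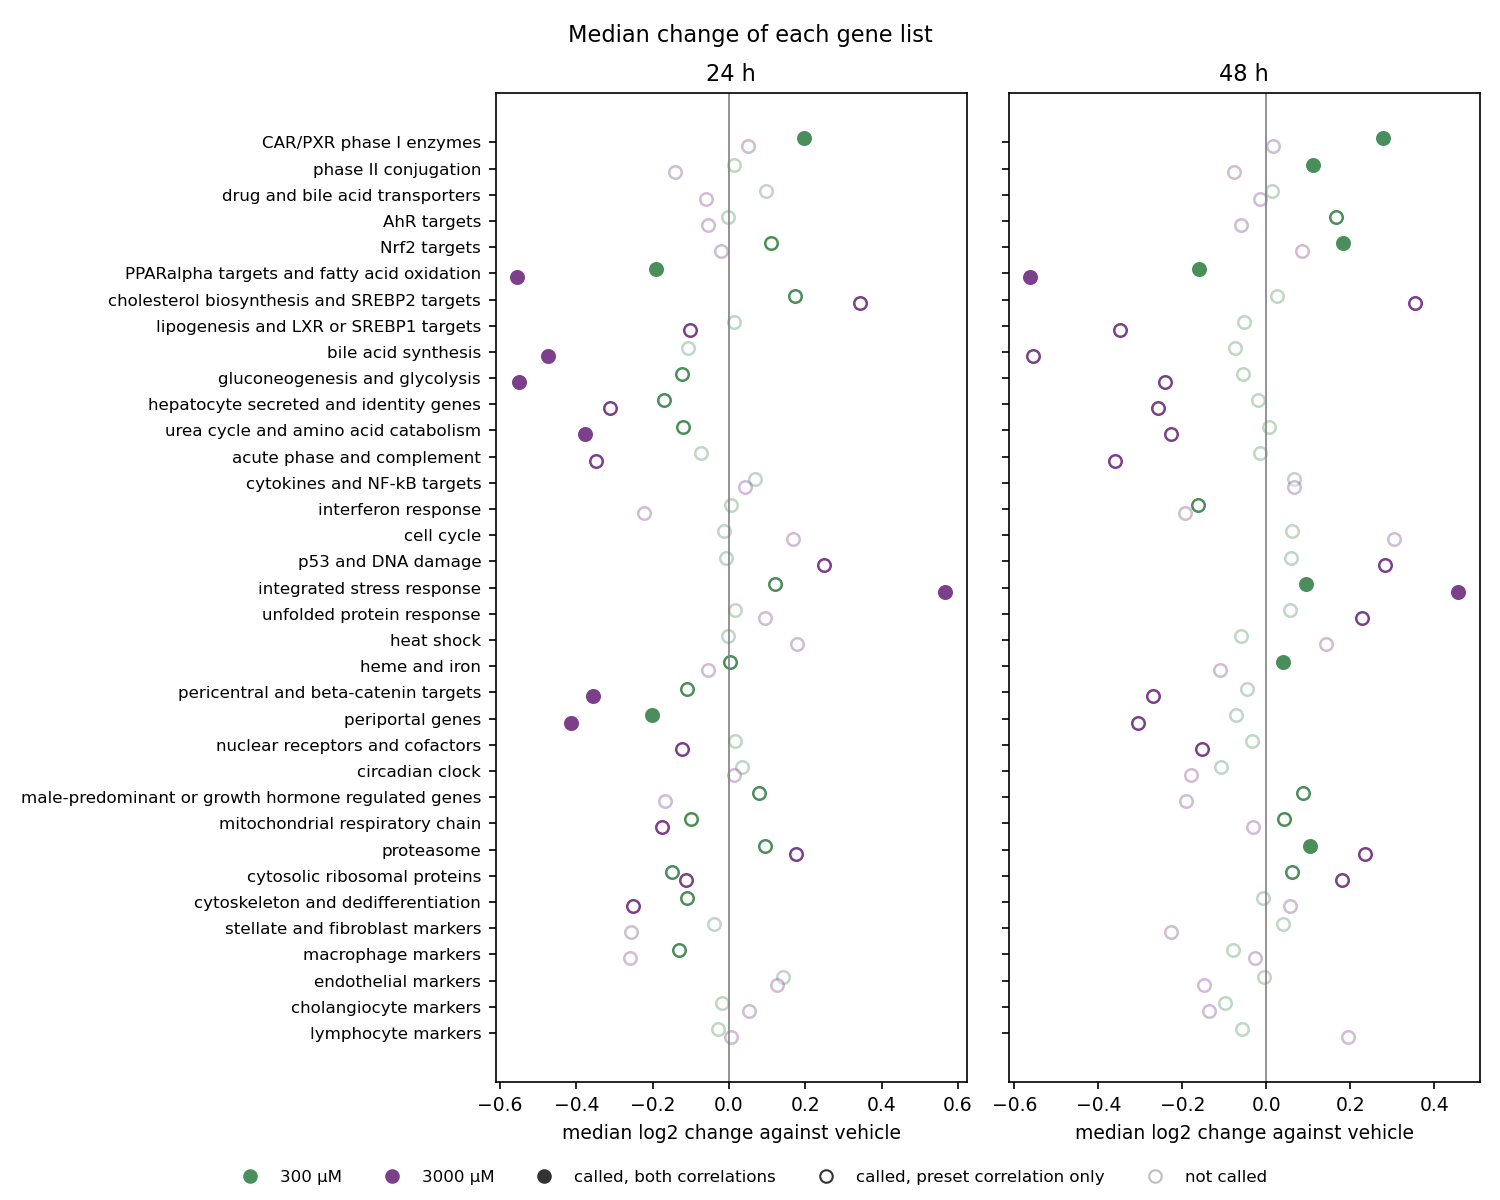
Median log2 change of the members of 35 gene lists against vehicle at 24 h and at 48 h, for 300 µM and 3000 µM. Filled points are lists called with the preset and the estimated correlation, open points with the preset one alone, pale points were not called, and PPARalpha targets had medians of -0.56 at 3000 µM at both times.

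Both doses were compared with the same vehicle arrays, which by itself makes their changes correlate. Across probe sets, which are not independent replicates, the log2 changes of the doses correlated with r = 0.458 at 24 h and 0.384 at 48 h. Simulated data with no effect gave 0.499 and 0.5 from the shared vehicle alone. The covariance was 0.042 and 0.038 against 0.017 and 0.017 simulated. Of the 285 probe sets higher at 300 µM at 24 h, 190 were also higher at 3000 µM, where independent lists of these sizes would share 49.3, and 19 were lower. Of 211 lower, 167 were lower at 3000 µM (31.2 for independent lists) and 8 higher. At 48 h 83 of 135 (26.3) and 95 of 120 (23.9) were shared, with 18 and 5 opposite. In 20 splits of the vehicle arrays, which gave each dose its own vehicle wells, the medians shared were 80.5 higher and 64 lower at 24 h (20.6 and 9.43 for independent lists) and 38 and 34 at 48 h (10.9 and 6.75). There r averaged 0.205 and 0.207 and the covariance 0.023 and 0.025, while simulations without effect shared 0 limma calls.

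The times were compared within each dose. At 300 µM, 84 probe sets were higher and 54 lower at both times (2.32 and 1.53 for independent lists), with no call in opposite directions. At 3000 µM, 1916 were higher and 1828 lower at both times (559 and 488), and 29 and 11 went from higher to lower and from lower to higher. The log2 changes correlated across probe sets with r = 0.261 at 300 µM and 0.730 at 3000 µM. No probe set's 300 µM effect differed between 48 h and 24 h by limma (0 at adjusted p under 0.05, lowest adjusted p 0.160, 1251 at unadjusted p under 0.05). With the compared groups alone in the fit 3 did, and with array weights 1. The 3000 µM effect differed for 688 probe sets, 229 higher and 459 lower at 48 h (42 and 190 of 232 with array medians centred), 33 of them by at least 2-fold (6 and 27). The rise of Ddit3 was larger at 48 h by 0.83 (adjusted p 0.00029), that of Rsad2 by 0.97 (0.0359) and that of Gstk1 by 0.39 (0.0219). Mtrf1 rose less at 48 h (-1.26, adjusted p 0.0454), and Nfe2 went from 1.69 to -1.32 (difference -3.01, SE 0.730, adjusted p 0.0166). Both are imprecise, with 24 h vehicle below the filter's level.

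The comparison of vehicle wells at 48 h with 24 h asked how far the cultures drifted without drug, and its list tests were not planned. In all, 1195 probe sets differed, 672 higher and 523 lower at 48 h, 56 by at least 2-fold (40 and 16). With array medians centred 735 differed, 268 higher and 467 lower, so the balance depended on the scaling. Of 15 CAR/PXR phase I enzymes, 9 fell and 6 did not pass (10 fell adjusted over the list alone). Cyp3a2 went from a mean log2 signal of 11.50 to 9.78 (camera adjusted p 4.41e-12, and 0.00136 with an estimated correlation). Of 14 male-predominant or growth hormone regulated genes, 8 fell and 6 did not pass (9 fell adjusted over the list alone). Cyp3a2 is on this list as well (camera adjusted p 4.52e-14, and 0.000743 with an estimated correlation). Of 32 genes of the urea cycle and amino acid catabolism, 12 fell and 20 did not pass (17 fell adjusted over the list alone). The list shifted lower (camera adjusted p 4.41e-12, and 0.000846 with an estimated correlation). Of 30 proteasome genes, 15 fell and 15 did not pass (21 fell adjusted over the list alone). This list also shifted lower (camera adjusted p 3.82e-12, and 0.00579 with an estimated correlation). Of 13 macrophage markers, 4 fell and 9 did not pass (4 fell adjusted over the list alone). They shifted lower too (camera adjusted p 8.52e-05, and 0.0035 with an estimated correlation). Of 28 integrated stress response genes, 11 rose, 1 fell and 16 did not pass (16 rose and 1 fell adjusted over the list alone). The stress genes shifted higher (camera adjusted p 1.02e-10, and 0.00206 with an estimated correlation). Of 5 cholangiocyte markers, 3 rose and 2 did not pass (3 rose adjusted over the list alone). These shifted higher (camera adjusted p 0.00154, and 0.0098 with an estimated correlation).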

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

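The tests of a general fall of hepatocyte genes, of targets falling back alike, of RNA quality, of the share of hepatocytes and of an even loss of transcripts, and the fit without the 2 arrays that stand apart, were chosen only after the results they bear on were seen.

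The shared probe set of Cyp2b1 and Cyp2b2 was far higher at 300 µM than at 3000 µM at both times, although the higher dose is the stronger exposure to the inducer. The tables argue against a scaling effect, since under quantile normalization and median centring the difference stayed between -3.37 and -3.59 on the log2 scale. They argue against wrong dose labels of single arrays, since 0 of 20 dosed arrays lay closer to the mean of the other dose, while exchanged labels of whole dose groups would leave that value as it is and stay open, though the lower dose would then be the one that changed more probe sets (5319 and 6539 against 496 and 255). A general fall of hepatocyte genes reached a list median of -0.256 at most, far from the fall of this probe set. That median does not speak to a strongly lowered subset, and Cyp7a1 and Cyp8b1 were also far lower at 3000 µM than at 300 µM. A fallback of all targets to the vehicle level is at odds with 3 of the 8 phase I enzymes that rose at 300 µM. Cyp2b3, Cyp2c6v1 and Cyp3a2 stayed above vehicle at 3000 µM at both times. A partial fallback is not excluded. The 5 of the 8 lower than at 300 µM (with Cyp2c6v1, without Cyp2b3 and Cyp3a2) cannot decide it, given how the 8 were chosen. A biological hypothesis also stays open: the fall of Nr1i3, the gene of the receptor CAR, by 1.39 and 1.31 on the log2 scale at 3000 µM may limit the response of this probe set, which no test here addressed, and dead or dying cells were not counted in the data.

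The effect of 3000 µM differed between 48 h and 24 h for 688 probe sets. The 2 arrays that stand apart are not the whole source, since 647 probe sets differed without them, though of these 458 were among the 688. The time change was larger at 3000 µM than in vehicle for 67.9% of the 688 (467 probe sets), against 54.6% of all probe sets tested. The exact binomial 95% bounds of this share, 64.2 and 71.4, treat probe sets as independent, which they are not. Arrays at 3000 µM and 48 h also had a mean residual standard deviation of 0.306, against 0.234 in 48 h vehicle, which favours larger changes there. The share leans against drift of the vehicle cultures alone but cannot exclude it. The count was 232 with array medians centred, 633 under quantile normalization and 410 to 976 leaving out 1 array. Of the 688, 303 moved further in the same direction at 48 h, 59 were larger at 24 h, 326 had opposite signs, and 40 of these were called in opposite directions at both times. A progressing response to the high dose is consistent with the 303, as a hypothesis.

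The list of hepatocyte secreted and identity genes shifted lower at 3000 µM with the preset correlation but not with an estimated one (adjusted p 0.0512 at 24 h and 0.204 at 48 h), and poorer RNA is argued against by the actin 3'/5' log2 ratio, which was higher than in vehicle by 0.079 at most, and by 0.0384 at 24 h. A lower share of hepatocytes stays open, since the drug could itself lower markers of other cell types. Of 5 lists, the 2 below 0 both times had no camera call: stellate cells and fibroblasts (-0.26 and -0.23) and macrophages (-0.26 and -0.027). An even loss of all hepatocyte transcripts is argued against by 8 of 14 members with vehicle means under 15 on the log2 scale, which lay more than 2 SE from the members' median change (-0.39 and -0.60) in the same direction at both times: Foxa2 (0.03 and 0.12), Hgd (0.41 and 0.61), Hnf4a (-0.17 and -0.43) and Serpinc1 (-0.20 and -0.11) above it, and F10, Foxa1, Plg and Prox1 (another probe set of which was at 0.053 at 24 h, adjusted p 0.912) below it. Foxa2, Hgd, Hnf4a and Serpinc1, like Cyp2b3 above, were named after their values were seen. Selective lowering of hepatocyte genes by the high dose may explain the pattern, and its relation to toxicity was not tested.

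Some arrays lay far from the other 4 of their group, by the rule that the gap to the nearest array was over 0.71 of the group's range. Chance gives about 1 such group in 20, and 52 of 788 pairs of a gene and a group (6.6%) and 7 of 36 array measures met it. Array 4 of the 48 h group at 3000 µM met it for most genes, 11, and besides these in its correlation with its group (0.9539), residual standard deviation (0.389), GAPDH 3'/5' log2 ratio (0.265), actin ratio (1.91) and hybridization control signal (14.32), and array 1 of the same group came next with 7. Array 1 of the 24 h vehicle group met it for the hybridization controls (13.90), and array 5 at 300 µM and 48 h for its median signal (413.4).

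Among the largest changes, the log2 signals that stood apart at 24 h were Cyp3a23-3a1 at 16.58 (vehicle array 1) and 16.39 (3000 µM array 4), Stmn1 at 8.78 (vehicle array 4), Nfe2 at 7.51 and Txnip at 12.15 (vehicle array 3), Rprm at 8.18 (300 µM array 3), Tnfrsf1b at 8.72 (3000 µM array 5), Clec14a at 2.07 (3000 µM array 3), Poteml2 at 11.70 and the shared Cyp2b probe set at 12.33 (3000 µM array 1, the others averaging 11.59). At 48 h they were Pla2g4b at 8.76 (vehicle array 4), Mapk4 at 4.46 (vehicle array 2), Poteml2 at 13.56 (vehicle array 3), Uggt1 at 12.96 (300 µM array 5), Klf11 at 10.44 (300 µM array 2), Shc4 at 10.16, Tmem255b at 7.10 and Cyp3a23-3a1 at 17.15 (3000 µM array 4), Calml4 at 5.33 (3000 µM array 5) and the shared Cyp2b probe set at 12.40 (3000 µM array 1, the others averaging 10.59). Another 32 pairs of a named list member and a group met the rule.

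Among the 688 probe sets whose 3000 µM effect differed between the times by its own test were those of Nfe2 (-3.01), Mtrf1 (-1.26), Rsad2 (0.97), Ddit3 (0.83) and Gstk1 (0.39). Lists whose 3000 µM effect differed with the preset correlation were cholesterol biosynthesis (median difference -0.204), unfolded protein response (0.142), mitochondrial respiratory chain (0.176), proteasome (0.0743) and cytosolic ribosomal proteins (0.257). At 300 µM they were phase II conjugation (0.153), Nrf2 targets (0.0637), cholesterol biosynthesis (-0.151), hepatocyte secreted genes (0.146), urea cycle (0.104), acute phase (0.0535), pericentral (0.12) and periportal genes (0.109), circadian clock (-0.155), mitochondrial respiratory chain (0.152), cytosolic ribosomal proteins (0.206) and cytoskeleton (0.0998). None of these 17 list differences was called with an estimated correlation.

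Probe sets without a gene name in the annotation took no part in the named results. Of 3294 tested, 1304 changed in at least 1 comparison of a dose with vehicle: 72 and 24 at 300 µM at 24 h and 48 h, and 800 and 1026 at 3000 µM, of which 5, 2, 86 and 147 reached 2-fold.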

How the results depend on the processing

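The fit without the 2 arrays that stand apart was chosen only after the data were seen, and the other alternatives were planned. At 3000 µM the counts of changed probe sets against vehicle were within 1.5 times the reported ones in all settings (leaving out 1 array, 4800 to 5005 and 5992 to 6532), and the cause was not tested for the moves below unless the setting itself gives it.

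With array medians centred, 227 and 124 probe sets changed at 300 µM at 24 h and 48 h, 735 between the vehicle groups (268 higher and 467 lower) and 232 differed in their 3000 µM effect between times, the doses shared 165 and 88 calls, and the times at 300 µM shared 71. It also moved the balance at 24 h to 3403 higher and 1680 lower at 3000 µM and to 2717 and 1365 against 300 µM, that at 300 µM at 48 h to 83 and 41 and that of the 3000 µM time difference to 42 and 190, and the median change of all probe sets to 0.075 at most. With no filter, 673 probe sets changed 2-fold at 3000 µM at 24 h and 362 differed in their 3000 µM effect, and with the stricter filter, which tests fewer probe sets, 7, 164 and 268 changed 2-fold (300 µM at 24 h, 3000 µM at 24 h and at 48 h) and the doses shared 278 calls at 48 h. With the compared groups alone in the fit, 482 changed at 300 µM at 48 h, 3 and 319 differed in the 300 µM and 3000 µM effects, and the doses shared 307 at 48 h. Array weights gave 615 and, 2-fold, 24 at 300 µM at 48 h, 1 difference in the 300 µM effect, and shared calls of 442 (doses at 48 h) and 239 (times at 300 µM). Without the 2 arrays these were 467 changed at 300 µM at 48 h, 1 difference and 340 shared by the doses at 48 h. Splitting the vehicle arrays, which leaves fewer arrays per comparison, gave 144.5 and 72 shared calls, and camera with an estimated correlation 22 list shifts in place of 119.

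Leaving out 1 array at a time gave 325 to 444 changes at 300 µM at 24 h (325 and 326 without 300 µM array 2 or 4), 168 to 266 at 48 h (168 without vehicle array 4), 0 to 1 differences in the 300 µM effect (1 without 24 h vehicle array 3), 410 to 976 in the 3000 µM effect, and 235 to 308 calls shared by the doses at 24 h (235 without 24 h vehicle array 2). The 3000 µM effect count was 410, 418, 429, 437 and 441 without 24 h 3000 µM array 1, 48 h vehicle array 3, 24 h 3000 µM array 4, 24 h vehicle array 2 or 48 h vehicle array 1, and 976 without 48 h 3000 µM array 1, against 688.

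Under quantile normalization 4 values changed sign: cytosolic ribosomal proteins at 3000 µM at 24 h (0.0684, adjusted p 0.0971), hepatocyte secreted genes in the time difference at 300 µM (-0.0225, 0.641) and at 3000 µM (-0.0703, 0.0178), and Rpl3 at 3000 µM at 24 h (0.0252, 0.491). Of 412 named gene calls, 63 ended with medians centred, 41 with no filter, 35 with the compared groups alone, 31 with eBayes without trend and robust estimation, 22 under quantile normalization, 14 with the mean of a gene's probe sets, 13 with a block, 12 each with array weights and without the 2 arrays, 7 with the covariate, 2 with an added 64 and none with an added 16, as did 351 of 4120 leaving out 1 array. Of 119 list calls, 18 ended under quantile normalization, 18 with the mean of probe sets, 6 with medians centred and 15 by fry, which called 136. Array medians of 349 to 424.9 against a lowest value of 0.251 limit folds of genes near the bottom of the scale.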

Other observations

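The splits of the arrays for the counts of probe sets and lists were planned, and the comparison with a gene's other probe sets was chosen only after the data were seen.

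The lists of this paragraph gave no camera call at 3000 µM. Of 6 AhR targets, Cyp1a2 (-0.48) and Tiparp (-0.34) fell at 3000 µM at 24 h (camera adjusted p 0.586) and Cyp1a1 (-0.51) and Cyp1a2 (-0.34) at 48 h (0.794), Cyp1a1 being at -0.20 (adjusted p 0.16) without array 5 at 3000 µM, and no limma call was made at 300 µM at 24 h (0.525). Of 14 cytokines and NF-kB targets, 1 rose, 2 fell and 11 did not pass at 3000 µM at 24 h (1 rose adjusted over the list alone). Ccl20 (-0.69) and Cxcl12 (-0.64) were lower and Nfkbia (0.39) higher there, without a shift of the list (0.771), and Ccl20 was at -0.38 (adjusted p 0.234) without array 5 at 3000 µM. At 48 h Cxcl11 (0.83), Icam1 (0.57) and Nfkbia (0.42) were higher and Tnfaip3 (-0.36) lower (0.531). Of 12 circadian clock genes, Npas2 (-1.16) fell and Cry1 (0.52), Clock (0.37) and Nr1d2 (0.26) rose at 3000 µM at 24 h (0.932). Npas2 (-1.33), Bmal1 (-0.41) and Bhlhe40 (-0.33) were among 4 clock genes that fell at 48 h, and 2, Clock (0.33) among them, rose (0.475, and 0.000749 by fry). Of 27 cell cycle genes, 7 rose and 20 did not pass at 3000 µM at 24 h, Ccne1 (1.43), Mcm4 (0.98), Aurkb (0.62) and Mcm7 (0.61) among them (0.151, and 5.06e-05 by fry). Ccne1 was at 0.80 (adjusted p 0.223) without vehicle array 1. Of 18 interferon response genes, 5 rose, 5 fell and 8 did not pass there, Rsad2 (1.49), Psmb8 (0.78) and Psmb9 (0.77) higher and Isg15 (-1.06) lower (0.932).

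At 3000 µM at 48 h heat shock genes were mixed, with Hsph1 (0.47) and Fkbp4 (0.39) higher and Cryab (-1.29) and Hspa1a (-0.87) lower (0.531). So were heme and iron genes, with Slc48a1 (0.49) and Blvrb (0.37) higher, Slc48a1 by 0.32 (adjusted p 0.00371) without array 4 at 3000 µM, and Hamp (-1.80) and Tfr2 (-0.40) lower (0.466). In the mitochondrial respiratory chain Ndufb5 (0.21) was higher and Sdha (-0.25), Sdhd (-0.20) and Uqcrfs1 (-0.17) lower (0.531). Among markers of other cells, Lox (-2.31) and Rgs5 (-1.07) were lower of 12 stellate and fibroblast markers (0.118), and C1qc (-1.23) was lower and Cd68 (0.80) higher of 13 macrophage markers (0.923). C1qc rested on array 1 at 3000 µM, at 3.96 against 7.74 for the others, and was at -0.47 (adjusted p 0.274) without it. Of 5 endothelial markers Esam (1.03) and Eng (0.47) were higher and Fcgr2b (-0.66) lower, with a median of -0.15, a mean of 0.10 and a test pointing lower (0.923). Of 5 cholangiocyte markers Onecut1 (-1.24) and Epcam (-0.14) were lower (0.436), and Onecut1 is also on the list of hepatocyte identity genes. The 3 measured lymphocyte markers gave no limma call against vehicle, with camera adjusted p values of 0.606, 0.932, 0.948 and 0.896.

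At 300 µM at 24 h small sets of genes moved in lists that did not shift. Mbl2 (0.34), Crp (0.30) and Il1r1 (0.30) rose and Serpina3n (-0.31) fell in acute phase and complement (0.138), and Xpc (0.28) and Mdm2 (0.23) rose in p53 and DNA damage (0.465). Herpud1 (-0.30), Edem1 (-0.26) and Hsp90b1 (-0.24) fell in the unfolded protein response (0.814). Cryab (-0.28) and Hspd1 (-0.19) fell and Chordc1 (0.26) rose in heat shock (0.605), and Lpin1 (-0.33) fell and Me1 rose in lipogenesis (0.795).

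Chance as the source of the counts was tested with 100 splits of the arrays of each comparison, the real one among them, and could be excluded where fewer than 5 reached the real count. For the counts of probe sets 1 split, the real one, did so: for 300 µM at 24 h (496 probe sets, highest other split 16, and 21 against 2 by 2-fold) and at 48 h (255 against 2, and 12 against 1), for 3000 µM at 24 h (5319 against 1291, and 439 against 80) and at 48 h (6539 against 3334, and 699 against 223), for 3000 µM against 300 µM (4336 against 735, and 5790 against 2742) and for the vehicle groups (1195 against 156). Other splits at 3000 µM that keep most treated arrays together also call many probe sets, because the groups differ strongly. For the difference of the 3000 µM effect between times, residuals were rearranged, and chance could be excluded (688 against 6). For the 300 µM effect the real count was 0, which all 100 rearrangements reach by construction (highest other 1), so this says nothing about chance. For list shifts, fewer than 5 splits had been asked for in each of the 4 comparisons with vehicle, which was not met, so chance could not be excluded for them as a set. The real count was reached by 5 splits at 3000 µM at 24 h (17 lists, highest other 17) and by 2 at 48 h (16 and 16), and by 1 at 300 µM at 24 h (17 and 16) and 4 at 48 h (12 and 12).

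The named genes had 98 other tested probe sets in the comparisons naming them, of which 94 had the same sign, 65 of these with a limma call. The other 29 of the same sign were not called, among them those of Cpt1a (-0.11 against -1.74) and Scd2 (-0.17 against -1.49) at 3000 µM at 48 h and of Klf11 at 300 µM at 48 h (-0.086 against -0.62), whose call ended with the mean of its probe sets (adjusted p 0.0642). Of the 4 with the opposite sign 1 was called, that of Sc5d at 3000 µM at 48 h (-0.23, adjusted p 0.0237, against 0.55). The others were those of Il1r1 at 300 µM at 24 h (-0.036 against 0.30), and of Prox1 (0.053 against -0.59) and Tgfb2 (0.12 against -0.81) at 3000 µM at 24 h.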
